A study of Homo sapiens with 8 samples.

How the data were processed

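Genomic DNA of sorted human CD8 T cells was measured by whole-genome bisulfite sequencing, in which unmethylated cytosines are converted and read as thymine while methylated cytosines are still read as cytosine. The 8 libraries cover 4 subsets with 2 libraries each: naïve cells (TN), stem cell memory cells (TSCM), central memory cells (TCM) and effector memory cells (TEM). Per the labels' protocols, libraries were made after bisulfite treatment with a random-primed methylation kit and amplified by PCR, and no molecular identifiers are mentioned, so reads are not independent molecules, and the limits given where no read was methylated (3 reads of the total of both libraries) cover counting error only. The replicate number of each library is the subject number in the labels. The labels write that number separately for each subset and do not say whether a number stands for the same donor in different subsets.

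The deposited tables hold 1 line per CpG with both strands merged, and no header. The authors' processing used CASAVA 1.7 and BSMAP with the human build hg19, per the submitters' processing notes. The read filters and the rule for removing duplicates are not given in the sources used here. The deposited methylated-read values are whole counts. The deposited coverage is an estimated count that is fractional at some CpGs and lies below the methylated reads at others, as an effective coverage adjusted for cytosine-to-thymine variants would be. In each library such adjusted coverage was found at 1.29% to 2.26% of autosomal CpGs. The deposited methylation fraction equalled the ratio of these values, limited to 1, within a tolerance of 0.00051 at 99.8% to 99.9% of CpGs with coverage. Coordinates are those of the deposited tables, counted from 1, in hg19.

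Only the 22 autosomes were used. A CpG with adjusted coverage in any library was left out of every library, which removed 11.3% of the 26448728 autosomal CpGs listed in at least 1 library. CpGs needed at least 5 reads in all 8 libraries, which left 8440842 CpGs. Mean CpG methylation was the mean of the CpG levels with equal weight for every CpG. Differences of these means were tested with two-sided exact permutation tests, which cannot reach 0.05 with 2 libraries against 2. For regional comparisons, methylated and unmethylated reads were summed over fixed 1 kb windows with at least 3 such CpGs. A read that covers several CpGs of a window was counted at each of them. Numbers of reads per window are therefore counts over CpGs, and the limits given where no read was methylated may be too low. There were 890898 windows, with a median of 6 measured CpGs and with median reads per window from 46 to 82 across libraries.

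Windows were tested with a quasi-binomial logistic model on the summed reads, with the 4 subset means fitted over all 8 libraries and 4 residual degrees of freedom. The Pearson overdispersion was moderated across windows with squeezeVar of limma 3.58.1 in R 4.3.3 and was never taken below 1. The prior overdispersion was 1.41 with 30.2 prior degrees of freedom. P-values came from a moderated F test and were adjusted by the Benjamini-Hochberg method within each of the 6 comparisons. A window was called changed at an adjusted p under 0.05 and a difference of subset means of at least 20 percentage points. Methylation levels are given in percent and differences in percentage points. These thresholds, the model and most alternatives were chosen before the data were examined. The other steps were written in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pyarrow 21.0.0 and matplotlib 3.10.9.

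The test was tested on simulated data with the real windows and coverage. The simulated spread was drawn from the test's own overdispersion estimates, and the tested subset equalled TN outside the changed windows. No genome-wide shift and no replicate batch were simulated, so the shares of false calls do not carry over to the real comparisons. For TEM against TN over 890898 windows, it called 41.9% of 5000 windows simulated with a difference of −20 points, 88.8% of those with −30, 97.2% of those with −40 and 99.6% of those with −50, and 65 of 16438 calls were false. For TSCM against TN, with the TSCM coverage, it called 40.3%, 86.2%, 96.1% and 99.4% of the same numbers of windows, and 70 of 16174 calls were false. With 4 unchanged subsets simulated in the same 890898 windows, 1 window was called in TCM against TN and 0 in each of the other 5 comparisons. In that simulation, unadjusted p-values lay under 0.05 in 4.41% to 5.01% of windows. Libraries of the same subset differed by more than the noise of independent counts, with a mean chi-square of 1.42 to 1.65 per window at 1 degree of freedom. Reads counted at several CpGs may add to this value. No library was therefore a copy of the other library of its subset. As nothing in the labels says how the donors were chosen, p-values refer only to these libraries. With 4 residual and 30.2 prior degrees of freedom, the spread used for a window came mostly from all windows together. Less of it came from the libraries at that window, so a small p does not show a small spread between them.

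The replicate-1 and the replicate-2 libraries listed 435 and 439 mitochondrial CpGs, as alignment to different mitochondrial reference sequences would give. The replicate number was therefore treated as a processing batch, and each number holds 1 library of every subset. Differences within each replicate number are printed beside the main values as within-batch values. Windows were called on the mean of the same libraries, so a shared direction within both numbers was likely beforehand and is no independent check.

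No gene positions in hg19 were used here, so the planned promoters, gene lists and named genes were not analysed. Regions are given by position instead. The rule for naming them replaced the planned rule for genes and was chosen after the data were seen. For each comparison and direction it takes the 3 called windows with the largest difference that moved the same way within both replicate numbers, and the 2 longest runs of adjoining called windows. CpG density was counted as all CpGs listed per window. Solo CpGs have no other listed CpG within 35 bp. Domains are fixed 100 kb intervals with at least 20 tested windows. Density classes, solo CpGs and domains were also chosen after the data were seen. No single CpG and no sex chromosome was analysed.

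Alternatives were a minimum of 3 or of 10 reads, a minimum of 5 CpGs per window, windows of 500 bp, difference thresholds of 10 and 30 points, limma on M-values (log2 of methylated reads plus 1 over unmethylated reads plus 1), the replicate number as a block, reads thinned to the mean coverage of the shallowest library, weighting each read equally, and leaving out each of the 8 libraries. Keeping CpGs with adjusted coverage, and counting the difference from the median of all windows, were added after the data were seen. The overlap between subsets without a shared library, the TSCM share of the TEM change in windows chosen in 1 replicate and measured in the other, and the simulation for TSCM were also added then. The planned overlap of simulated unchanged subsets gave no comparison, because each simulated list held 0 or 1 window.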

Results

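DNA methylation was measured across the genome in naïve CD8 T cells, which have not yet met their antigen, and in 3 memory subsets. TSCM cells are self-renewing memory cells with many surface features of naïve cells, TCM cells recirculate through lymphoid organs, and TEM cells carry immediate effector function. The design asks how far each memory subset differs from naïve cells, and how the memory subsets differ from each other. Mean coverage of listed autosomal CpGs was 10.4 and 8.95 reads in the TN libraries, 8.62 and 5.34 in TSCM, 10.1 and 9.62 in TCM, and 10.2 and 10.8 in TEM, for replicates 1 and 2. The second TSCM library was the shallowest, and 51.4% of its autosomal CpGs had at least 5 reads, compared with 69.7% to 83.1% in the other libraries.

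Memory cells had lower methylation than naïve cells across the genome. Mean CpG methylation over 8440842 CpGs was 79.9% ± 0.942 in TN, 76.8% ± 0.740 in TSCM, 72.8% ± 0.360 in TCM and 70.8% ± 0.273 in TEM (SD, n = 2). The difference from TN was −3.12 points in TSCM, −7.06 in TCM and −9.11 in TEM. Within replicate 1 these differences were −2.98, −6.14 and −8.25 points, and within replicate 2 they were −3.26, −7.98 and −9.97 points. Each difference exceeded the SDs of the subsets compared, and the TN and memory libraries did not overlap. Each difference gave the smallest p that a two-sided exact permutation test of 2 libraries against 2 allows, which cannot reach 0.05.

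**Figure D1:**
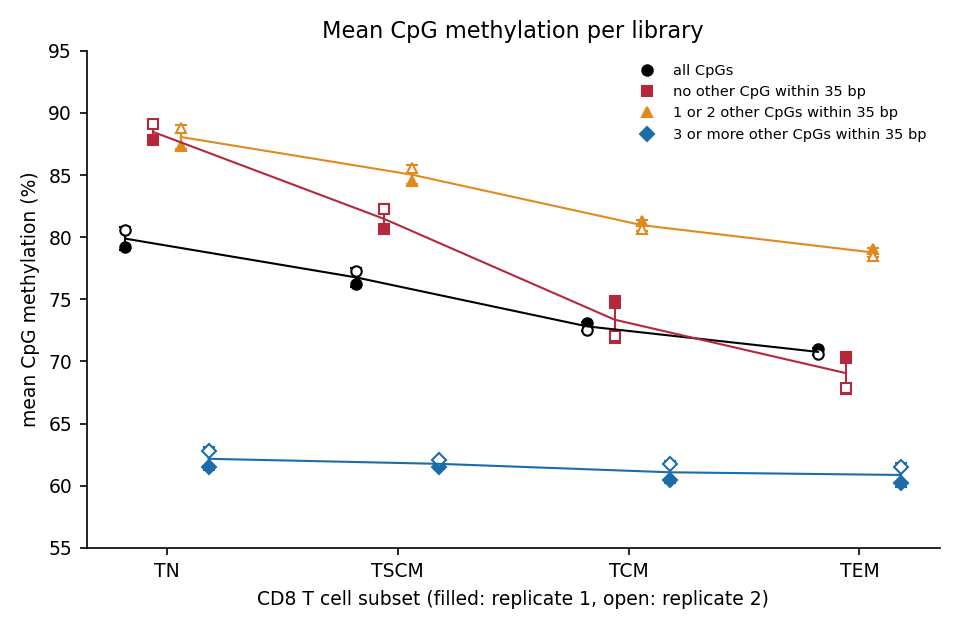
Mean CpG methylation in percent (vertical axis, starting at 55) for each library of the 4 subsets, for all CpGs and for CpGs grouped by the number of other CpGs within 35 bp. Filled and open symbols are replicates 1 and 2, and lines join the subset means with bars of 1 SD (n = 2); CpGs with no other CpG nearby went from 88.5% in TN to 69.1% in TEM, and CpGs with 3 or more stayed between 60.9% and 62.2%.

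The loss was unevenly spread over CpG densities. In windows with 3 to 9 CpGs per kb, mean methylation was 90.7% ± 0.927 in TN, 84.9% ± 1.14 in TSCM, 77.9% ± 1.45 in TCM and 74.3% ± 1.28 in TEM (SD, n = 2). In windows with 20 to 39 CpGs per kb it was 86.8% ± 0.982 in TN and 79.5% ± 0.0246 in TEM. In the densest windows, with 40 or more CpGs per kb, it was 41.1% in TN and 41.6% ± 1.23 in TEM, with differences of 0.198 points within replicate 1 and 0.811 within replicate 2, less than the spread between replicates. That mean pools windows of low and high methylation: among the densest windows with at least 90% in the other TN library, TEM was at −4.32 points from TN in replicate 1 (13226 windows) and −5.09 in replicate 2 (12557 windows). TEM was called lower than TN in 36.0% of the sparsest windows, 20.5% of those with 10 to 19 CpGs per kb, 7.17% of those with 20 to 39 and 0.564% of the densest. Gains ran the other way, from 0.418% of the sparsest windows to 1.79% of the densest, where 802 windows were higher and 252 lower in TEM. These shares also depend on the TN level, because highly methylated windows leave little room for a gain and windows of low methylation little room for a loss.

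**Figure D2:**
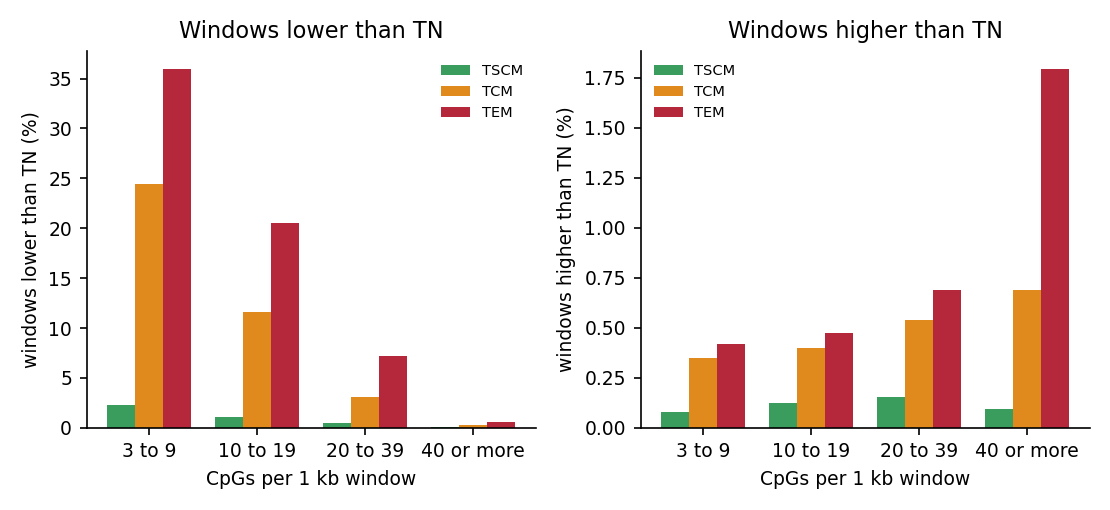
Share of 1 kb windows called lower (left) or higher (right) than TN in percent, by the number of CpGs in the window, for TSCM, TCM and TEM. The share lower in TEM goes from 36.0% in the sparsest to 0.564% in the densest windows, and the share higher from 0.418% to 1.79%; the vertical scales differ.

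TSCM cells differed from naïve cells mostly by loss. Of 890898 windows, 37215 passed the adjusted p at any size, and 10127 were lower and 1088 higher in TSCM by at least 20 points. With the difference counted from the median of all windows, −2.87 points, 7380 were lower and 1403 higher. Smaller differences were widespread, with TSCM lower within both replicate numbers in 92.2% of 15426 domains of 100 kb. The lower windows averaged 89.2% ± 0.499 in TN and 60.5% ± 0.0903 in TSCM, and the higher windows 33.2% ± 1.68 in TN and 62.8% ± 1.25 in TSCM (SD, n = 2). All but 2 of the 11215 changed windows moved the same way within both replicate numbers, which the call on the same libraries made likely. In windows chosen at 50 points or more in replicate 1, TSCM losses shrank from −58.4 to −46.9 points in replicate 2, and gains from 55.2 to 34.9. In windows chosen in replicate 2, losses shrank from −58.8 to −38.1 points in replicate 1, and gains from 57.2 to 36.7. Methylation in TSCM was −28.6 points from TN in the windows called lower, which were chosen by the 20-point threshold. It was −7.28 points 1 kb away, −4.81 points 5 kb away and −3.97 points 50 kb away, compared with the median of −2.87 points over all windows.

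The window with the largest loss in TSCM was on chromosome 4 from 48298001 to 48299000, with 96.9% in TN and 7.65% ± 7.87 in TSCM over 4 measured CpGs (SD, n = 2; adjusted p = 3.26e-09). The difference was −82.5 points within replicate 1 and −96.1 within replicate 2, and the window was also low in TCM, at 9.28%, and in TEM, at 4.32%. On chromosome 12 from 27975001 to 27976000, methylation went from 88.2% ± 6.34 in TN to 7.50% ± 10.6 in TSCM over 3 CpGs (adjusted p = 1.24e-05). A 4 kb run of adjoining losses, on chromosome 16 from 2010001 to 2014000, went from 78.9% ± 0.245 in TN to 44.6% ± 2.19 in TSCM over 74 CpGs. Among gains, a window on chromosome 10 from 121300001 to 121301000 went from 14.4% ± 8.61 to 79.4% ± 13.8 (adjusted p = 1.68e-04). The longest run of gains covered 7 kb on chromosome 17 from 75427001 to 75434000, at 19.3% ± 1.39 in TN, 46.8% ± 5.16 in TSCM and 76.4% ± 1.21 in TEM over 119 CpGs. A second run of gains on chromosome 13, from 100066001 to 100071000, went from 30.8% ± 0.547 in TN to 70.7% ± 8.19 in TSCM and 87.6% ± 0.999 in TEM.

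The number of TSCM windows rested on every library of the comparison: 3740 were called without TN replicate 1, 2925 without TN replicate 2, 2455 without TSCM replicate 1 and 6942 without TSCM replicate 2. It was 824 of 379059 windows after thinning the reads to the shallowest library and 4949 with limma on M-values, with losses above gains in each.

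TCM cells had lower methylation than naïve cells at 104400 windows and higher at 3875, and 104385 and 3875 of these moved the same way within both replicate numbers. Lower windows averaged 90.2% ± 0.771 in TN and 62.1% ± 3.66 in TCM, and higher windows 36.8% ± 1.78 in TN and 67.6% ± 3.37 in TCM (SD, n = 2). The largest loss was on chromosome 2 from 144992001 to 144993000, from 94.4% ± 1.99 in TN to 1.47% ± 2.08 in TCM (adjusted p = 8.55e-09). On chromosome 6 from 76206001 to 76207000, with 10 measured CpGs and 82 to 172 reads per library, methylation was 97.9% in TN, 37.8% ± 17.2 in TSCM and 5.44% ± 6.45 in TCM (adjusted p = 3.58e-14), with TCM at −86.5 points from TN within replicate 1 and −98.4 within replicate 2. A 7 kb run of losses on chromosome 6 from 31541001 to 31548000 averaged 81.5% ± 5.65 in TN and 69.9% ± 0.740 in TSCM, compared with 37.1% ± 11.1 in TCM and 32.6% ± 2.68 in TEM. An 8 kb run on chromosome 20 from 50146001 to 50154000 went from 85.5% ± 0.352 in TN to 47.5% ± 10.1 in TCM.

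The longest run of gains in TCM covered 10 kb, and the longest run of losses 8 kb. The run of gains on chromosome 14 from 99663001 to 99673000 averaged 41.7% ± 1.68 in TN, 76.0% ± 5.24 in TCM and 80.7% ± 3.05 in TEM over 113 CpGs (SD, n = 2). On chromosome 2 from 85069001 to 85070000, 0 of 38 reads, counted per CpG, were methylated at 3 CpGs in TN. If these counts were independent, they would allow a share of up to 7.89%. TCM had 84.9% ± 14.0 there (adjusted p = 2.05e-06). Losses made up 96.4% of the TCM changes, and 86.6% when the difference was counted from the median of all windows, −6.59 points. Thinned reads gave 33986 changed windows of 379059, fewer partly because fewer windows could be tested.

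TEM cells were farthest from naïve cells, with 174808 windows lower and 5132 higher, of which 174778 and 5129 moved the same way within both replicate numbers. Lower windows averaged 90.7% ± 0.840 in TN and 61.1% ± 2.69 in TEM, and higher windows 33.8% ± 1.55 in TN and 64.9% ± 2.62 in TEM (SD, n = 2). TEM losses stood in areas of loss: 5 kb away from a lower window the difference from TN was still −15.6 points, compared with a median of −8.73 points over all windows. Whether TEM losses were wider than TSCM losses against their own medians was not tested. The longest run of losses covered 12 kb on chromosome 10 from 125948001 to 125960000, from 93.4% ± 0.701 in TN to 63.4% ± 3.57 in TEM. On chromosome 17 from 34207001 to 34208000, methylation was 96.4% ± 0.323 in TN, 41.1% ± 12.6 in TSCM, 24.9% ± 13.9 in TCM and 0 of 89 reads in TEM, which allows a share of up to 3.37% (adjusted p = 9.59e-12). On chromosome 6 from 152492001 to 152493000 it was 95.8% ± 0.494 in TN and 0 of 38 reads in TEM, which allows up to 7.89% (adjusted p = 5.78e-08). The reads in both windows are counted per CpG, so both limits may be too low.

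At gains in TEM the difference from TN was 31.2 points in the called windows, 6.59 points 1 kb away and −2.18 points 5 kb away. It was −6.96 points 50 kb away, so the surroundings of gains also stood above the median of −8.73 points over all windows. Whether gains were narrower than losses against that median was not tested. A 9 kb run on chromosome 5 from 133459001 to 133468000 averaged 10.3% ± 1.88 in TN, 36.7% ± 1.03 in TSCM, 48.7% ± 3.18 in TCM and 66.8% ± 2.38 in TEM over 97 CpGs (SD, n = 2). On chromosome 4 from 109387001 to 109388000, TN had 1.67% ± 2.36, TSCM 58.7% ± 0.845, TCM 62.6% ± 5.75 and TEM 94.0% ± 4.35 (adjusted p = 5.30e-10). The 10 kb run on chromosome 14 was also the longest run of gains in TEM. All runs named here moved the same way within both replicate numbers, while the named windows did so by the rule that chose them. Losses made up 97.1% of the TEM changes, and 85.8% when the difference was counted from the median of all windows, −8.73 points. With thinned reads 60420 of 379059 windows were called, 94.3% of them lower.

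**Figure D3:**
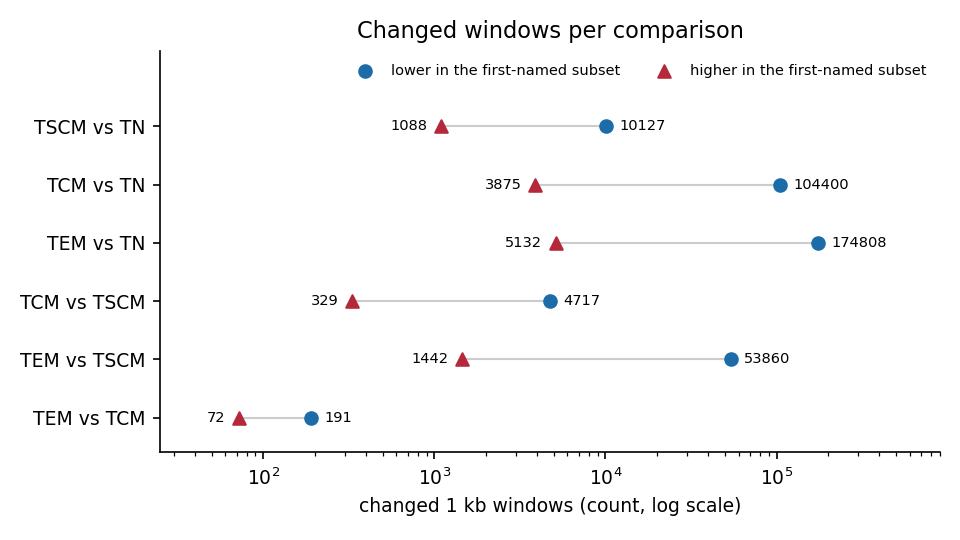
Number of 1 kb windows called lower (circles) or higher (triangles) in the first-named subset of each comparison, on a log scale, out of 890898 tested. Losses outnumber gains in all 6 comparisons, from 174808 against 5132 in TEM vs TN to 191 against 72 in TEM vs TCM.

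**Figure D4:**
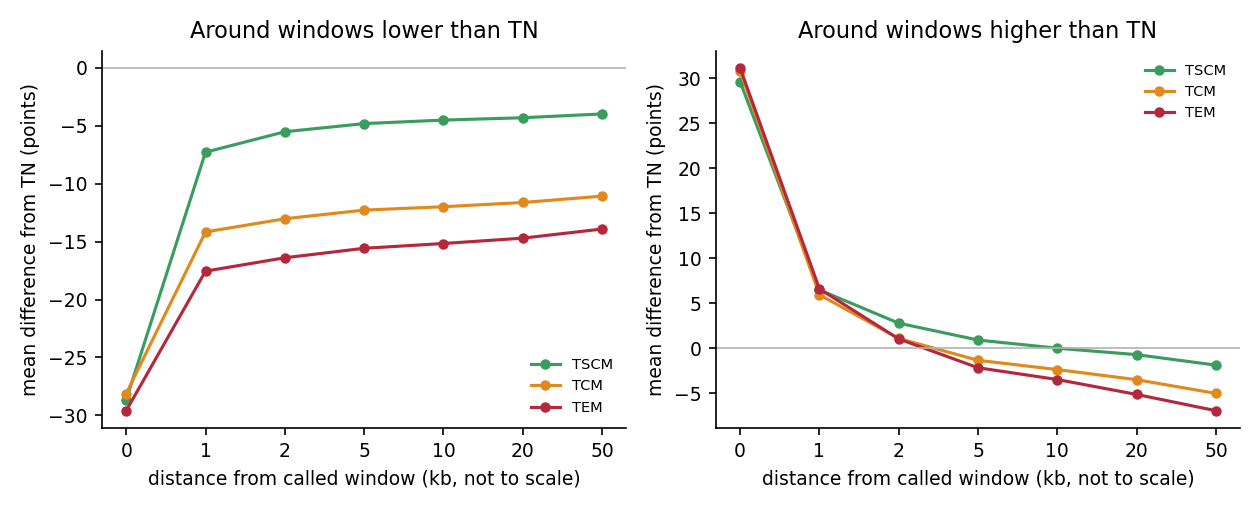
Mean difference from TN in percentage points in the called windows (distance 0) and in windows 1 to 50 kb away on either side, for windows called lower (left) and higher (right). Around lower windows the difference at 5 kb is −4.81 points in TSCM, −12.3 in TCM and −15.6 in TEM; the vertical scales differ.

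The changes of the 3 memory subsets overlapped. Of the 10127 windows lower in TSCM, 9185 were also lower in TCM and 9539 in TEM, and 8958 were lower in all 3 memory subsets. Independent lists of these sizes would share 1187 and 1987 windows. Of the 1088 windows higher in TSCM, 1008 were also higher in TCM and 1009 in TEM, where independent lists would share 4.73 and 6.27. TCM and TEM shared 93301 lower windows, compared with 20485 for independent lists. These lists share both TN libraries. The numbers for independent lists, here and below, let every window change. Windows of high methylation leave little room for a gain, and the windows higher in TSCM had a median of 32.8% in TN. Part of the excess over independent lists can therefore come from the TN level alone, and how much was not tested. With no library in common, of the 28872 windows at least 20 points lower in TSCM replicate 1 than in TN replicate 1, 23370 were also at least 20 points lower in TEM replicate 2 than in TN replicate 2, where independent lists would share 6889. The other pairing, TSCM replicate 2 and TEM replicate 1, shared 21484 of 32780, where independent lists would share 5718. For gains, these pairings shared 1478 of 3248 and 1476 of 3563 windows, compared with 25.4 and 23.1 for independent lists. These windows were taken by size alone, without a test.

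**Figure D5:**
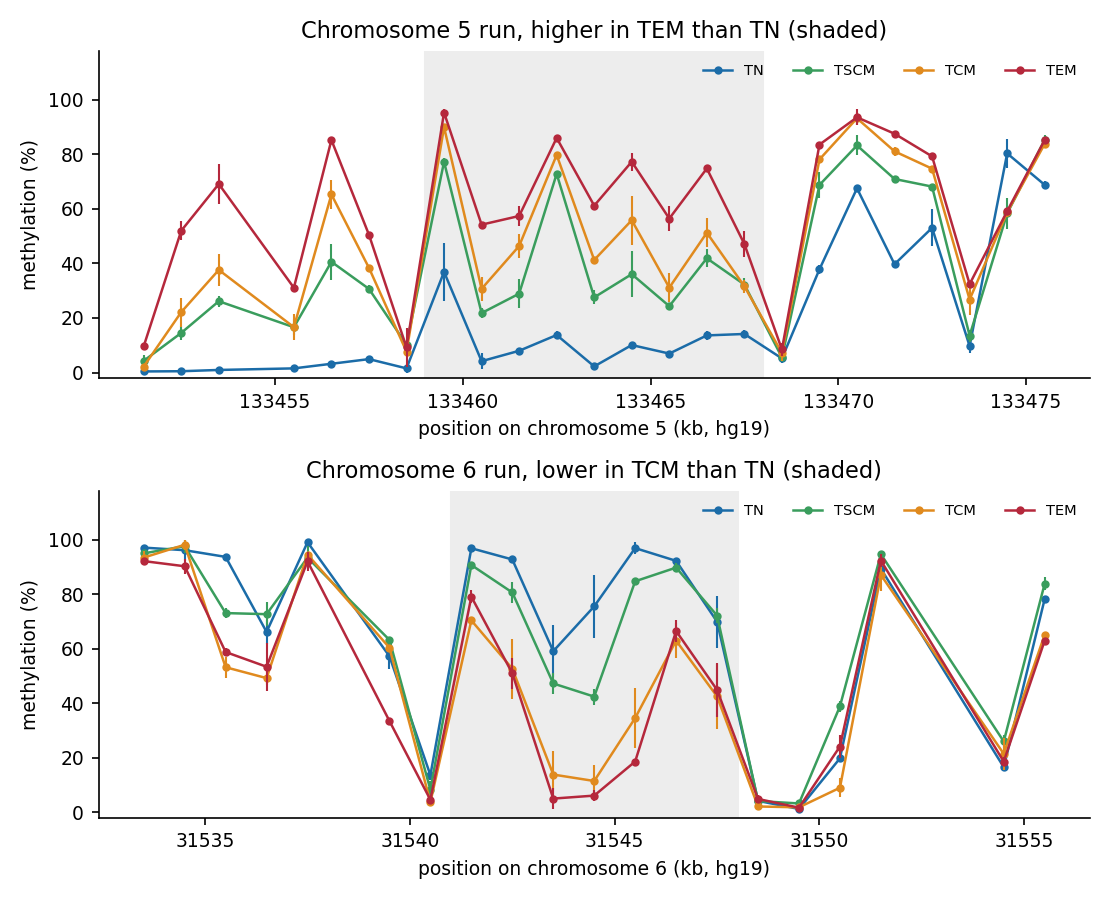
Methylation in percent of 1 kb windows along 2 regions in hg19, with points at subset means of 2 libraries, vertical bars from the lower to the higher library, and lines that also bridge windows without enough CpGs. In the shaded chromosome 5 run the means are 10.3% in TN, 36.7% in TSCM, 48.7% in TCM and 66.8% in TEM; in the shaded chromosome 6 run they are 81.5%, 69.9%, 37.1% and 32.6%.

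TCM and TEM were each compared with TSCM. TEM was lower than TSCM in 53860 windows and higher in 1442, and 53851 and 1440 of these moved the same way within both replicate numbers. TCM was lower in 4717 and higher in 329, all of them the same way within both. With the difference counted from the median of all windows, TEM was lower than TSCM in 25656 and higher in 3170 windows, and TCM was lower in 2957 and higher in 572. In the windows lower in TEM, TSCM was at 82.6% ± 1.52 and TEM at 55.7% ± 3.14, with TN at 90.2% ± 0.821 (SD, n = 2). The largest difference was on chromosome 2 from 38909001 to 38910000, with 87.5% ± 9.65 in TSCM and 13.9% ± 3.93 in TEM (adjusted p = 8.68e-05). On chromosome 3 from 46413001 to 46414000, methylation was 94.4% ± 1.72 in TN, 74.6% ± 7.62 in TSCM, 44.1% ± 4.57 in TCM and 5.83% ± 5.23 in TEM (adjusted p = 5.73e-06). The 7 kb run on chromosome 6 was the longest loss of TCM against TSCM, and its 6 kb part from 31542001 to 31548000 was among the longest losses of TEM against TSCM, at 66.8% ± 0.151 in TSCM and 25.9% ± 3.67 in TEM. On chromosome 12 from 4082001 to 4083000, TSCM was below TN, at 18.2% ± 9.05 compared with 46.3% ± 6.11, and TEM was above both at 80.8% ± 11.4 (adjusted p = 1.20e-05 for TEM against TSCM). On chromosome 10 from 121297001 to 121300000, a run of gains was at 2.60% ± 0.571 in TN, 25.9% in TSCM and 58.1% ± 4.25 in TCM, which was higher than TSCM by 28.4 points within replicate 1 and 36.1 within replicate 2.

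These comparisons were less firm than those with TN. With limma on M-values, 0 windows passed in either. An unadjusted p under 0.05 was found in 133404 of 890898 windows in TCM against TSCM and 239604 in TEM against TSCM. Both counts exceed the share of 0.05 that windows without a difference would give. The TCM count was 34 without TSCM replicate 1, 243 without TSCM replicate 2, 128 without TCM replicate 2, 2461 without either TN library and 9385 without TCM replicate 1, and 1 with thinned reads. The TEM count was 19681 without TSCM replicate 1, 18657 without TSCM replicate 2, 21770 without TEM replicate 2 and 11073 with thinned reads.

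TCM and TEM had the smallest difference in mean CpG methylation of the 6 comparisons, at −2.05 points in TEM, −2.12 within replicate 1 and −1.99 within replicate 2. TEM was lower in 191 windows and higher in 72, all the same way within both replicate numbers, and in 165 and 90 with the difference counted from the median of all windows. The lower windows averaged 82.5% ± 0.907 in TN, 61.5% ± 0.264 in TCM and 33.2% ± 1.86 in TEM (SD, n = 2). A 5 kb run on chromosome 20 from 24930001 to 24935000 was at 63.1% ± 5.51 in TCM and 33.7% ± 6.13 in TEM over 74 CpGs. Another 5 kb run on chromosome 19 from 51872001 to 51877000 was at 46.6% ± 1.58 in TCM and 18.4% ± 5.46 in TEM. On chromosome 14 from 99754001 to 99755000, TCM had 59.3% ± 5.08 and TEM 11.9% ± 8.85 (adjusted p = 6.22e-04). Of the gains, 3 kb of the chromosome 17 run, from 75429001 to 75432000, were at 50.2% ± 1.39 in TCM and 73.5% ± 1.09 in TEM. A window on chromosome 10 from 6449001 to 6450000 was lowest in TCM, at 33.3%, compared with 89.4% ± 9.02 in TN, 56.5% ± 0.891 in TSCM and 79.7% ± 2.05 in TEM (adjusted p = 1.28e-03 for TEM against TCM, with differences of 49.9 and 42.9 points within replicates 1 and 2). The count of 263 changed windows was 152 without either TN library, 130 without TCM replicate 1 and 139 without TEM replicate 2. It was 2 of 190917 windows with at least 10 reads per CpG, and 0 with thinned reads and with limma on M-values. With thinned reads, 22573 of 379059 windows had an unadjusted p under 0.05. That is little above the share of 0.05 that windows without a difference would give. With limma on M-values, 36635 of 890898 windows did so, which is below that share.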

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

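The tests in this part were chosen after the result was seen. Mitochondrial CpGs, which are outside the comparisons, carried methylated reads in every library, far above the level that a count of 0 allows. The share of methylated reads on them was 44.5% in TN replicate 1, 62.8% in TN replicate 2, 49.8% in TSCM replicate 1, 59.2% in TSCM replicate 2, 44.3% in TCM replicate 1, 68.0% in TCM replicate 2, 45.0% in TEM replicate 1 and 67.1% in TEM replicate 2. The shares were 44.3% to 49.8% in replicate 1 and 59.2% to 68.0% in replicate 2. Incomplete bisulfite conversion of whole libraries is argued against, because the 4470 least methylated of the 44704 windows with 40 or more CpGs per kb had a median of at most 0.488% in any library. Removal of duplicate reads at a capped depth may have changed the shares: mean mitochondrial coverage was 123 to 140 and varied 1.14-fold between libraries, while autosomal coverage varied 2.02-fold, but no table shows how the cap acts on methylated and unmethylated reads, so this stays open. No biological explanation was tested.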

How the results depend on the processing

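Counting the size from the median of all windows, keeping CpGs with adjusted coverage, the overlap without a shared library and the simulation for TSCM were chosen after seeing the data. Losses outnumbered gains under every alternative that gave calls. The cause of each shift below was not tested, except where another difference threshold set it. Alternatives with fewer or more windows also changed the share of windows called. In TSCM against TN that share was 1.26% in the main setting, 0.382% with 10 reads and 0.217% with thinned reads. Counts follow in the order TSCM, TCM and TEM against TN, TCM and TEM against TSCM, and TEM against TCM, where all 6 are given. With 10 reads per CpG, 190917 windows gave 729, 15947, 27272, 1, 7534 and 2 changed windows. With 3 reads, 1330730 windows gave 19611, 191904, 313212, 8326, 91544 and 410. With 5 CpGs per window, 580935 windows gave 5477, 50645, 93146, 2770, 28345 and 175. Thinned reads gave 824, 33986, 60420, 1, 11073 and 0 of 379059 windows. In the last, 22573 lay at an unadjusted p under 0.05, little above the share of 0.05 that no difference would give. A threshold of 10 points gave 28605, 275445, 378872, 14384, 136073 and 435, and one of 30 points 3583, 32500, 66187, 1331, 13758 and 87. Limma on M-values gave 4949 in TSCM against TN and 0 in TCM against TSCM, TEM against TSCM and TEM against TCM. In these last comparisons 133404, 239604 and 36635 of 890898 windows lay at an unadjusted p under 0.05. The count of 36635 is below the share of 0.05 that no difference would give. The TCM and TEM counts against TN with limma were within 1.5 times. Windows of 500 bp moved only TCM against TSCM past 1.5 times, to 2373. Counting from the median gave 54973 in TCM and 85608 in TEM against TN and 28826 in TEM against TSCM. Leaving out 1 library gave 2455 to 11342, 86033 to 128544, 159130 to 198069, 34 to 9385, 18657 to 61496 and 130 to 377; a lone library was assumed to vary like the other groups. Keeping adjusted CpGs left every count within 1.5 times. The difference in mean CpG methylation was −2.61 (10 reads), −3.43 (3 reads), −2.39 (reads weighted equally) and −2.62 (thinned) in TSCM, and −7.89 (10 reads) and −7.85 (thinned) in TEM; without 1 library it ranged from −3.79 to −2.45 in TSCM, −7.72 to −6.39 in TCM and −9.78 to −8.44 in TEM.

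With the replicate number as a block, 12858, 109089, 180336, 6259, 57957 and 358 windows were called, and no count moved by over 1.5 times; the paired differences in mean methylation were −3.12, −7.06 and −9.11. The numbers are not known to pair donors: the correlations of same-numbered deviations over domains were 0.140, 0.117 and 0.101 for TN with TSCM, TCM and TEM, −0.163 and −0.138 for TSCM with TCM and TEM, and 0.580 for TCM with TEM. The 18 named windows of the comparisons with TN, at 16 distinct places, passed the test in all 222 values under the alternatives that measured them. The 18 among memory subsets, at 17 distinct places, passed in 157 of 223 values, and 0 values reversed. All were named for the largest differences in the same data, and many values reuse the same reads, so passing was favoured beforehand. Of the 36 named windows, thinned reads measured 4 and the minimum of 5 CpGs measured 9. Of 318 values for the 24 named runs, at 22 distinct places, 33 moved by more than 1 SD and 0 reversed. The share of lower TSCM windows in little-changed domains ranged from 43.0% with 3 reads (60.6% of all windows) to 82.9% with thinned reads (82.7%). Without a shared library, the shared windows of each pair of memory subsets stayed above the number for independent lists in both directions and both pairings. That number takes no account of the TN level. Promoters, gene lists and named genes, with their alternatives, were not run. At the depth of the libraries, simulated differences of −30 points passed the adjusted p in 87.1% of windows in TSCM against TN and 89.4% in TEM against TN, and those of −20 points in 63.6% and 67.5%; no simulation varied the depth.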

Other observations

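The tests on solo CpGs, domains, the TSCM share of the TEM change and the genome-wide loss were chosen after the result was seen. The loss per CpG was largest at isolated CpGs. At 1979119 solo CpGs, mean methylation was 88.5% ± 0.907 in TN, 81.5% ± 1.16 in TSCM, 73.4% ± 1.90 in TCM and 69.1% ± 1.71 in TEM (SD, n = 2). At CpGs with 1 or 2 others within 35 bp, which started near the same level, it was 88.1% ± 0.970 in TN and 78.8% ± 0.391 in TEM. At CpGs with 3 or more others, which started lower, it was 62.2% ± 0.927 in TN and 60.9% ± 0.947 in TEM. The difference there was −1.31 points within replicate 1 and −1.29 within replicate 2. Of 8534 lower TSCM windows in 100 kb domains, 57.4% stood where the rest of the domain was under 5 points lower than TN, compared with 73.0% of all windows in that comparison. The values were 7.89% of the lower windows and 31.7% of all windows in TCM, and 4.09% and 21.0% in TEM. The TSCM contrast was absent without TN replicate 2 (80.9% of lower and 80.8% of all windows), without TSCM replicate 1 (81.4% and 81.4%) and with thinned reads (82.9% and 82.7%). Domains at least 10 points below TN numbered 45 of 15426 in TSCM, 5847 in TCM and 8057 in TEM. Without the called TSCM windows, the domain differences of TSCM replicate 1 and TEM replicate 2 from their own TN libraries correlated at 0.887 over 15311 domains, and those of TSCM replicate 2 and TEM replicate 1 at 0.818. These pairs share no library, and domains are not independent replicates. In the tenth of domains with the most TEM loss in replicate 2, −22.7 points, TSCM replicate 1 was at −6.99 points, and in the tenth with the least, −1.49 points, it was at −0.0929. In the other pair, TSCM replicate 2 was at −6.42 points where TEM replicate 1 was at −18.7, and at −0.987 where it was at −1.11.

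Where TEM had moved at least 50 points, TSCM stood between naïve and effector memory cells. Over the 6055 windows that TEM lost, means were 88.9% ± 0.677 in TN, 63.2% ± 0.673 in TSCM, 43.8% ± 5.11 in TCM and 31.2% ± 4.45 in TEM (SD, n = 2). TSCM was within 10 points of TEM in both replicates at 54 of these windows and within 10 points of TN at 123. Over the 397 windows that TEM gained, means were 17.8% ± 0.909 in TN, 49.9% ± 1.75 in TSCM, 68.3% ± 4.25 in TCM and 77.8% ± 2.38 in TEM. The median TSCM change was 42.2% of the TEM change at losses and 54.1% at gains, but these windows were chosen by their TEM change. In windows chosen in 1 replicate and measured in the other, TEM losses shrank from −57.7 to −53.9 points and from −58.3 to −41.8 points. The mean TSCM change was then 44.2% and 47.2% of the TEM change at losses, and 55.2% and 53.5% at gains.

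Lower methylation across the genome in memory subsets may be technical or may belong to the subsets. Read depth is argued against for TEM, since its median difference from TN was −6.91 points with every library thinned to the same mean coverage. TN and TEM had similar coverage before thinning, so thinning could change little between them. For TSCM, with the shallowest library, the median was −2.24 points with thinned reads and −2.87 points without. The bound used for TEM could not be reached there, because the TSCM median lay short of it without thinning too. The thinned median also covers fewer windows, 379059 compared with 890898, so this test cannot decide on depth for TSCM. The TSCM difference in mean CpG methylation was −2.98 points within replicate 1 and −3.26 within replicate 2, which holds the shallowest library. Depth stays open for TSCM. Over-conversion of methylated cytosines was assumed to act on all CpGs alike, which was not tested. Among windows of at least 90% in the other TN library, the TEM difference depended on CpG density. Under 10 CpGs per kb it lay −6.47 points from that at 20 to 39 CpGs per kb in replicate 1, and −7.64 points in replicate 2. This argues against over-conversion only if the assumption holds. The naïve or memory state stays among the open explanations as a hypothesis, beside the purity of the sort and differences between donors, which were not tested.

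The middle position of TSCM could come from a mixture of naïve and more differentiated cells in the sort. Each window would then show the same share of the loss, and the shares measured in replicate 1 and replicate 2 would not go together from window to window. They correlated at 0.310 (95% interval 0.287 to 0.332) over the 6055 windows for a mixture of TN and TEM, and at 0.301 (0.262 to 0.338) over 2173 windows for a mixture of TN and TCM, compared with −0.0160 and −0.0336 in simulated mixtures. The fifth of windows with the lowest TEM-like share in replicate 1 had a share of 33.3% in replicate 2, and the fifth with the highest had 54.3%. A correlation of at most 0.1 in size was set beforehand for a mixture, and one above 0.3 for arguing against it. Both values lie barely above 0.3, and their intervals reach below it. A mixture of TN with TEM alone or with TCM alone is therefore only weakly argued against as the whole cause. The simulated mixtures held counting error only, and the intervals treat windows as independent. A smaller admixture and mixtures of more than 2 cell types stay open.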
